A study of Mus musculus with 12 samples.

How the data were processed

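RNA was measured in 12 mouse cerebellar libraries of 3 kinds, with 4 libraries each: normal astrocytes, astrocytes derived from tumor, and tumor granule neuron progenitors (GNPs), the tumor cells of medulloblastoma, a cancer of the cerebellum. Per the labels, individual cells were taken by laser capture microdissection from thin frozen sections, in which a laser lifts chosen cells from a fixed slide. The RNA was reverse transcribed and amplified as short 3′ end cDNA, re-amplified, and made into libraries by Nextera XT tagmentation. A method of this kind reads mostly the 3′ end of each transcript, so a count does not scale with gene length, and amplification from few cells adds dropouts and noise between libraries. The labels do not say how cells were recognised for capture. A sample sheet deposited beside the counts describes the normal libraries as adult astrocytes of the cerebellum and the tumor-derived ones as astrocytes of tumor. The GNP names there carry a suffix that its first GNP entry spells out as cultured. The labels give laser capture for every library, so whether the GNPs had been in culture is not settled by the sources used here. Age and culture, where they differ, follow the groups and cannot be separated from cell type.

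The values are raw read counts per gene as the authors deposited them, in 1 table with a column for each library. Per the submitters' processing notes, read quality was examined with FastQC and reads were aligned with STAR to the mouse build mm10. The program that counted reads, its annotation and whether it used strand are not given in the sources used here, so antisense and overlapping genes and near-identical paralogs cannot be told apart in these counts. Members of the ribosomal protein, hemoglobin and class II antigen presentation families are uncertain for that reason. The table held 47284 lines, because genes with several database identifiers were repeated with identical counts. Removing 767 repeats left 46517 Ensembl genes. For 27 genes a spreadsheet had turned the symbol into a date, and all 27 symbols were restored through the Ensembl identifier. Gene coordinates are those of the table, on mm10. Of these genes, 46005 were also in GENCODE M21 for the same build, and the coordinates of 45983 overlapped. The 37 mitochondrial genes had a total of 0 counts, so no share of mitochondrial RNA could be given. No column of other samples was present in the table.

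Each library held between 8154401 and 12626596 counts. At this depth 3 counts, the upper limit that a count of 0 allows, corresponded on average to 0.294 normalised CPM (counts scaled by library size) in normal astrocytes, 0.339 CPM in tumor-derived astrocytes and 0.315 CPM in GNPs. A fold difference against a group in which every library was at 0 is therefore given as a lower bound, with that group set to its floor of 3 counts per library. The reads carry no molecular identifiers, so floors cover counting error only.

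Libraries were grouped by the cell type in the labels. Replicates were numbered in accession order and the numbers pair nothing. The labels tie no library to an animal, and captured regions may share an animal, in which case p-values over libraries are too small. All p-values measure only the spread between these libraries, part of which may be technical. Before any average was taken, libraries of 1 group were compared with a chi-square test on genes with at least 10 counts in a pair, and separately on those with at most 49. GNP libraries 1, 2 and 4 differed from each other far less than libraries of 1 group did elsewhere. They are therefore counted as 1 sample in every GNP mean ± SD (n = 2: their mean, and library 3). The planned fits kept all 4 GNP libraries, and a second fit, added after the data were seen, summed libraries 1, 2 and 4 into 1. In comparisons with GNPs, a gene is said to be higher or lower only when it passed both fits.

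Differential expression was tested with edgeR 4.0.16 (R 4.3.3) by its quasi-likelihood F-test with robust dispersion, on TMM-normalised counts of the 14393 genes that passed filterByExpr (minimum count 10, minimum total 15). The model held 3 group means over all 12 libraries (9 residual degrees of freedom, or 7 with GNP libraries combined), and the common biological coefficient of variation was 0.66 (0.722 combined). P-values were adjusted by the Benjamini-Hochberg method and called at 0.05, with no fold threshold. Every adjusted p of a gene given without another name comes from this edgeR fit of all 12 libraries. Against GNPs such values are too small if the close trio is a single sample. Log2 fold changes carry their standard error. Levels are TMM-normalised CPM, with mean ± SD over libraries.

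A total of 22 gene lists of cell types and pathways with at least 5 tested members were examined with camera (limma 3.58.1, correlation between genes preset to 0.01), with Benjamini-Hochberg adjustment over the lists. Camera was repeated with an estimated correlation, and fry was run beside it. The lists, the groups, the tests, the rule for named genes and most of the alternatives were fixed before the data were examined. That rule took, for each comparison, the 8 largest fold changes in each direction among called genes whose libraries did not overlap between the groups, leaving out model names, ribosomal protein genes and pseudogenes. It added called members of each list with the smallest adjusted p, from which the text picks, and in every comparison Gfap, Aqp4, Slc1a3, Sox9, Atoh1, Zic1, Gli1, Ptch1, Mki67, Il4, Igf1 and Shh. A few further genes are named as chosen after their values were seen.

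Similarity was measured as the mean Spearman correlation of log2 CPM (prior count 2) between libraries across all tested genes, which are not independent replicates. The difference between tumor-derived astrocytes' similarity to normal astrocytes and to GNPs was tested by an exact two-sided permutation over the 70 assignments of the 8 normal and GNP libraries. The position of tumor-derived astrocytes between the other groups was the median, over genes called between normal astrocytes and GNPs, of the log2 distance from normal astrocytes divided by the distance from normal astrocytes to GNPs. It is 0 at the level of normal astrocytes and 1 at that of GNPs.

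The analysis was first tested on simulated counts of the 14393 genes. They were drawn from the real dispersions and library sizes and from a mean of each gene pooled over all groups. Of 100 genes changed 4-fold, 29 were called between tumor-derived and normal astrocytes, 29 between tumor-derived astrocytes and GNPs, and 22 between normal astrocytes and GNPs. Of 100 genes changed 16-fold, 65, 67 and 65 were called in the same order, with 1 unchanged gene called in each comparison. No other genes were changed, whereas 33 to 44.2% of tested genes were called in the real comparisons. The adjusted cutoff depends on that share, so these rates do not give the recovery in the real data. In 10 simulations without any change, at most 1 gene was called and 0 of the 22 lists passed. Genes were drawn independently there, while estimated correlations in the real lists reached 0.574. The list tests were therefore not tried on members that vary together. When 3 GNP libraries were redrawn from 1 sample in such simulations, a median of 9 genes (at most 17) was called between tumor-derived astrocytes and GNPs and of 11 (at most 31) between normal astrocytes and GNPs, against 0 in both when those libraries were combined.

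Alternatives were DESeq2 1.42.0 (Wald test), limma voom with quality weights, other scaling factors (RLE, TMMwsp, upper quartile), no filter or a filter of 10 CPM in 4 libraries, a fit of only the 2 groups compared, a fit without robust dispersion, a prior count of 0.5, Pearson correlation and leaving out each library in turn. Data were prepared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.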

Results

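The data were counts of RNA-seq reads per gene from 4 libraries of normal astrocytes, 4 of tumor-derived astrocytes and 4 of tumor GNPs of the mouse, each made, per the labels, from cells taken by laser capture microdissection. Astrocytes are the star-shaped glia that support neurons, and GNPs are the dividing precursors of cerebellar granule neurons from which this medulloblastoma grows. The design sets tumor-derived astrocytes against both other groups. Total counts were 8838441 to 11287457 in normal astrocytes, 8679971 to 12626596 in tumor-derived astrocytes and 8154401 to 8673023 in GNPs. Genes with at least 1 count numbered 14768 to 16306, 19174 to 20460 and 16633 to 17938 per library in the same order. Ribosomal protein genes took 5.49 to 8.83% of counts in normal astrocytes, 19.61 to 22.6% in tumor-derived astrocytes and 20.45 to 23.83% in GNPs. GNP libraries 1, 2 and 4 were far closer to each other than other libraries of 1 group. Over genes with few counts, chi-square per degree of freedom of the 3 pairs was 1.21 to 1.62, against 4.2 to 14.58 for the other 15 pairs within groups. Over all genes with at least 10 counts it was 1.43 for libraries 2 and 4 and 7.52 and 6.59 for library 1 with each of these, against 24.03 to 184.33 elsewhere, so that library 1 differed beyond counting noise. Only 5 to 41 genes were at 0 in 1 library of such a pair and at 10 or more counts in the other, against 171 to 1627 elsewhere. These 3 libraries were counted as 1 sample in each GNP mean (n = 2).

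Tumor-derived astrocytes lay between the other groups on the first principal component and apart from both on the second, and many genes of astrocytes and of tumor cells were at intermediate levels in them. Their mean Spearman correlation across genes was 0.748 with GNP libraries and 0.693 with normal astrocyte libraries, while normal astrocytes and GNPs correlated at 0.621. The difference of -0.0554 between the first 2 values had an exact permutation p of 0.0286 (two-sided), the smallest that 70 assignments allow. With GNP libraries 1, 2 and 4 counted as 1, it was -0.0663 with an exact permutation p of 0.0667, the smallest that 15 assignments allow, so that this test could not pass 0.05. It weakened to -0.0347 (exact permutation p = 0.0571) without normal replicate 3 and to -0.0345 (p = 0.0571, exact permutation) without GNP replicate 3. Its size depended on the filter, at -0.0254 with no filter on low counts and -0.0968 with a filter of CPM 10. On a scale where normal astrocytes are at 0 and GNPs at 1, the 3423 genes called higher in normal astrocytes by the planned fit alone had a median position of 0.44 ± 0.029 (SD over 4 libraries), with quartiles of 0.05 and 0.831. The 2933 called higher in GNPs by that fit had a median position of 0.729 ± 0.014, with quartiles of 0.396 and 1.034. With the GNP trio combined, the positions were 0.47 over 1929 genes and 0.782 over 2023. These genes were chosen for a difference between normal astrocytes and GNPs, which by itself favours a position between them. On the first principal component, which held 45.5% of the variance, tumor-derived libraries were at 20.58 to 33.95, normal astrocytes at -167.71 to -148.99 and GNPs at 101.88 to 147.94. On the second, with 24.1%, they were at -127.24 to -118.86, against 24.6 to 80.37 and 28.78 to 96.03.

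**Figure D1:**
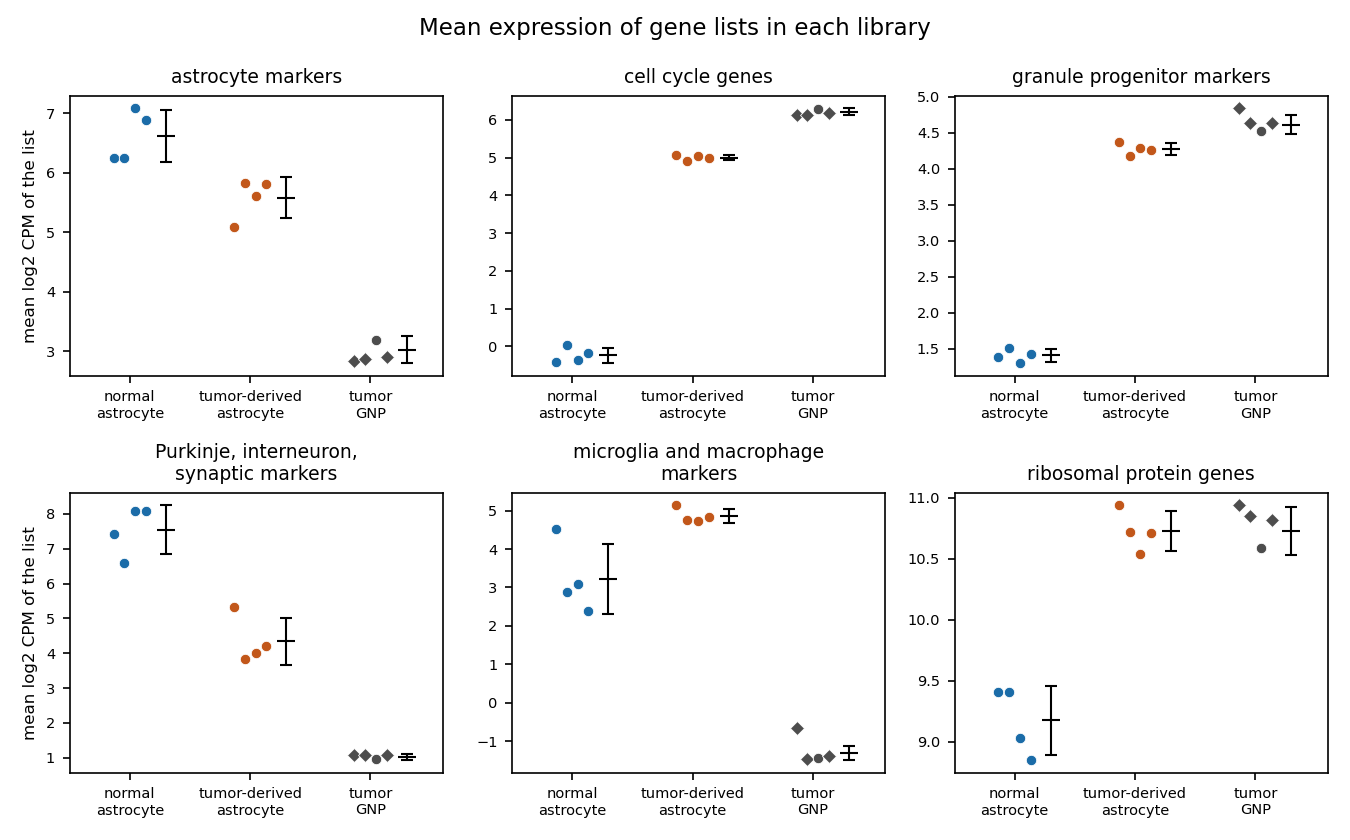
Mean log2 CPM over the tested members of 6 gene lists (y axes) in each library of the 3 groups (x axes), with circles for libraries, diamonds for GNP libraries 1, 2 and 4, and black bars for the mean ± SD (n = 4 libraries; in GNPs n = 2, the mean of the diamonds and library 3). Cell cycle genes averaged -0.23 in normal astrocytes against 5.0 in tumor-derived astrocytes and 6.22 in GNPs, while astrocyte markers averaged 6.61, 5.58 and 3.03.

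Against normal astrocytes, tumor-derived astrocytes carried high levels of cell cycle, granule progenitor and Hedgehog target transcripts and lower levels of many markers of mature astrocytes and neurons. Mki67, a marker of dividing cells, was at 872 ± 147 CPM in tumor-derived and 0.275 ± 0.424 CPM in normal astrocytes (n = 4 each). Aldoc, a glycolytic enzyme on the astrocyte list, fell from 6956 ± 3299 to 479 ± 198 CPM. The normal libraries also held neuronal transcripts, and whether their Aldoc came from astrocytes or neurons was not tested. Gli1, a transcription factor and direct target of Hedgehog signalling, rose from 1.47 ± 2.21 to 65.0 ± 5.63 CPM. Of 14393 genes tested, 2980 were higher and 2776 lower in tumor-derived astrocytes (edgeR, adjusted p under 0.05), and 2506 and 2297 with the GNP trio combined in the same model. With upper quartile factors the counts were 3444 and 2289, so the balance between directions depends on the scaling.

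Cell cycle genes formed the group that moved most. Of its 40 members 33 rose and 0 fell (34 and 0 adjusted over the list alone), with a median log2 fold change of 5.23, or 4.91 with 5 members that were at 0 in normal astrocytes set to their bound. The camera test gave an adjusted p of 1.41e-33, and an adjusted p = 2.48e-05 with an estimated correlation. Mki67 had a log2 fold change of 11.7 ± 0.62 (adjusted p = 1.14e-07), which was 13.53 without normal replicate 2, the library that held most of its few normal counts. Mcm3, a subunit of the replicative helicase, rose by 8.74 ± 0.54 (adjusted p = 2.15e-07), or 9.37 without normal replicate 2. The 8 genes of largest rise were at 0 in every normal library. They were Igfbpl1, Chaf1b, Hsd11b2, E2f2, Pdlim3, Tnnt1, Cdca5 and Ube2c, with adjusted p of 1.37e-07 to 0.000667. Chaf1b assembles chromatin behind the replication fork, E2f2 is a cell cycle transcription factor, and Cdca5 and Ube2c act in mitosis. Igfbpl1 (518 ± 201 CPM) was at least 1760-fold higher and Ube2c (62.9 ± 28.3 CPM) at least 214-fold higher. Tnnt1 stood at 236 CPM in tumor-derived replicate 1 and at 10.7 to 16.8 CPM in the others, and its fitted log2 fold change of 12.37 was 10.03 without that replicate.

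Granule progenitor markers rose as a group, with 11 of 15 members higher and 0 lower (11 and 0 adjusted over the list alone). The median was 2.4 on the log2 scale (camera adjusted p = 4.83e-06, and adjusted p = 0.00579 with an estimated correlation). Barhl1, a homeobox gene of granule progenitors, rose by 4.67 ± 0.50 (adjusted p = 1.6e-05) and Zic4 by 2.4 ± 0.27 (adjusted p = 2.07e-05). Nhlh1 was at 43.2 ± 24.8 CPM against 0, at least 147-fold higher (adjusted p = 3.87e-06). Atoh1, the transcription factor that defines granule progenitors, was at 6.47 ± 4.54 CPM against 0, at least 22-fold higher (adjusted p = 6.05e-05), with 13.2 CPM in tumor-derived replicate 4 and 3.74 to 4.99 in the others. Its fitted log2 fold change was 8.96, and 8.35 without that replicate. Zic1 was 97.3 ± 4.93 against 127 ± 48.3 CPM (log2 fold change -0.38 ± 0.25, adjusted p = 0.245). Of 13 Hedgehog pathway genes 7 rose and 2 fell (7 and 3 adjusted over the list alone), with a median of 1.83 (camera adjusted p = 0.000959, but adjusted p = 0.156 with an estimated correlation). Gli1 rose by 5.44 ± 1.0 (adjusted p = 0.000968), or 7.23 without normal replicate 4, and Ccnd2, a cyclin driven by the pathway, by 8.09 ± 0.75 (adjusted p = 5.35e-06). Ptch1, the Hedgehog receptor and usually itself a target, fell by 1.45 ± 0.41 on the log2 scale, to 8.44 ± 1.51 CPM (adjusted p = 0.0132).

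Many astrocyte markers fell, with 13 of 24 lower and 3 higher (15 and 3 adjusted over the list alone). The median was -1.2 with quartiles of -2.1 and -0.25 (camera adjusted p = 0.000959, but adjusted p = 0.299 with an estimated correlation). Aldoc fell by 3.86 ± 0.47 on the log2 scale (adjusted p = 4.84e-05) and Atp1b2, a sodium pump subunit, by 2.61 ± 0.34 (adjusted p = 7.19e-05). Gjb6, a gap junction protein of mature astrocytes, changed by -4.2 ± 0.62 (adjusted p = 0.000214), or -4.81 without tumor-derived replicate 2. Slc1a3, the glutamate transporter GLAST, was 85.5 ± 20.4 against 304 ± 280 CPM (-1.83 ± 0.56, adjusted p = 0.0201). That call was lost without normal replicate 3 (-1.09, adjusted p = 0.0919) and without tumor-derived replicate 2, 3 or 4 (adjusted p of 0.0609, 0.0559 and 0.0571), and in a fit of the 2 groups alone (adjusted p = 0.0547). Aqp4, the water channel of astrocyte endfeet, was 8.79 ± 2.63 against 20.7 ± 9.47 CPM (-1.24 ± 0.55, adjusted p = 0.0885). It passed with DESeq2 (adjusted p = 0.0355), and over 16 alternatives its adjusted p ranged from 0.0355 to 0.242. Sox9 was low in both, at 0.825 ± 0.273 and 1.84 ± 1.83 CPM (adjusted p = 0.323). Aldh1l1, a folate enzyme used as a general astrocyte marker and chosen here after its values were seen, was 274 ± 58.4 in tumor-derived and 241 ± 153 CPM in normal astrocytes (log2 fold change 0.18 ± 0.41, adjusted p = 0.748).

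**Figure D2:**
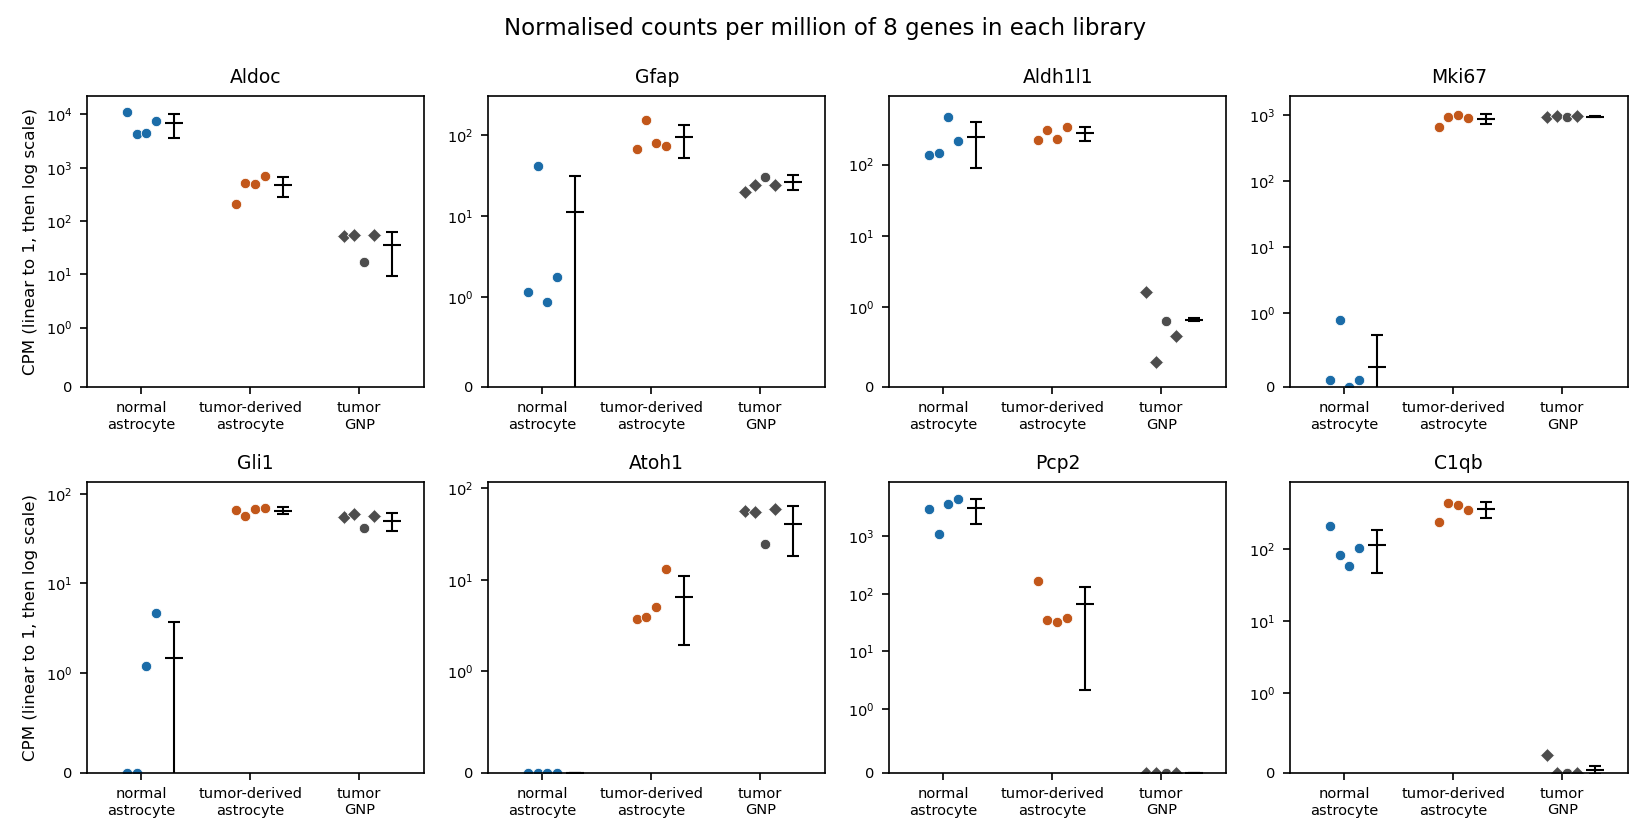
CPM of 8 genes (y axes, linear to 1 and logarithmic above) in each library of the 3 groups (x axes), with circles for libraries, diamonds for GNP libraries 1, 2 and 4, and black bars for the mean ± SD (n = 4 libraries; in GNPs n = 2). Aldh1l1 was at 241 and 274 CPM in normal and tumor-derived astrocytes and 0.843 CPM in GNPs, Mki67 at 0.275, 872 and 945 CPM, and 1 normal library carried nearly all of that group's Gfap.

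Gfap, the intermediate filament raised in reactive astrocytes, was 92.4 ± 40.3 CPM in tumor-derived and 11.2 ± 19.9 CPM in normal astrocytes (log2 fold change 3.05 ± 1.01, adjusted p = 0.0284). Normal replicate 2 stood at 41.1 CPM and the other normal libraries at 0.946 to 1.76 CPM, and without it the log2 fold change was 6.19. The call was lost without normal replicate 4 (adjusted p = 0.0554), without tumor-derived replicate 2 (adjusted p = 0.0696) and in a fit of the 2 groups alone (adjusted p = 0.0595). Of 11 genes raised in all kinds of reactive astrocyte 3 rose and 0 fell, with the same counts adjusted over the list alone (median 1.39, camera adjusted p = 0.216). Timp1, an inhibitor of metalloproteases, was 45.7 ± 31.6 against 0.716 ± 0.796 CPM (adjusted p = 0.000886), a log2 fold change of 6.0 ± 1.09 that was 7.02 without normal replicate 2. Of 8 genes tied to the A1 reactive state 3 rose and 0 fell, likewise adjusted over the list alone (median 1.36, camera adjusted p = 0.387). Among them was the immunoproteasome subunit Psmb8 (2.31 ± 0.51, adjusted p = 0.00318; 2.97 without normal replicate 3). Of 6 genes tied to the A2 state 1 rose and 0 fell, also adjusted over the list alone (median 0.24, camera adjusted p = 0.96). Bergmann and radial glia markers gave 1 higher and 3 lower of 11 by either adjustment (median -1.03, camera adjusted p = 0.96). The 1 that rose was Nes, the filament of neural precursors, by 4.87 ± 0.37 (adjusted p = 1.16e-06). Of 17 genes tied to astrocyte specification 4 rose and 1 fell by either adjustment (camera adjusted p = 0.96). The median of -0.3 and mean of -0.08 were negative where the test pointed up. Nfib, a nuclear factor required for gliogenesis, rose by 1.57 ± 0.22 (adjusted p = 0.000155). It also differed from GNPs (adjusted p at most 0.0164 over 16 alternatives) but was not among the genes higher than in both other groups in both fits.

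Markers of Purkinje cells, interneurons and mature synapses were mostly lower in tumor-derived astrocytes, while genes of granule neurons and of neurons in general went both ways. Of the former, 15 of 16 fell and 1 rose by either adjustment (median -4.07, camera adjusted p = 1.44e-08, but adjusted p = 0.156 with an estimated correlation). Itpr1, a calcium release channel abundant in Purkinje cells, fell from 1247 ± 722 to 30.2 ± 15.4 CPM (adjusted p = 9.54e-06), and the member that rose was the glutamate transporter Slc17a6. It was at 19.6 ± 2.92 against 0.0244 ± 0.0488 CPM (adjusted p = 1.16e-06), with its only normal count in replicate 4. All libraries labelled normal astrocyte thus held neuronal transcripts, with Pcp2, a Purkinje cell gene, at 3053 ± 1444 CPM. Granule neuron and general neuronal genes gave 4 higher and 9 lower of 18 by either adjustment (median -1.15, camera adjusted p = 0.0232, but adjusted p = 0.347 with an estimated correlation, 0.0724 without normal replicate 2 and 0.111 with a filter of CPM 10). Dcx and Tubb3, genes of young neurons, rose by 6.95 ± 0.53 and 2.5 ± 0.28 (adjusted p of 1.32e-06 and 2.5e-05). Snap25, of the synaptic vesicle machinery, changed by -5.75 ± 0.39 (adjusted p = 5.3e-07) and Gabra6, a receptor subunit of mature granule neurons, by -7.05 ± 0.65 (adjusted p = 2.32e-05). The 8 genes of largest fall were Plk5, Krt25, Cds1, Htr1b, Hhatl, Comp, Ggact and RP23-187D22.3, with adjusted p of 2.31e-05 to 0.006. Plk5 is a kinase of neurons and glia, and Cds1 (356 ± 121 against 0.505 ± 0.355 CPM) makes a precursor of phosphoinositides. Htr1b, Ggact and RP23-187D22.3 were at 0 in every tumor-derived library and at least 21.4-fold, 17.6-fold and 15.3-fold lower. Without normal replicate 4 the fitted log2 fold change of Htr1b was -7.96 rather than -9.12. Comp had its only 2 tumor-derived counts in replicate 2. For Hhatl the log2 fold change was -8.93, and -8.35 without normal replicate 3 or -9.54 without tumor-derived replicate 4, and for Plk5 it was -10.35, and -11.18 without tumor-derived replicate 2.

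Some immune and matrix genes rose in the tumor-derived astrocyte libraries, but many members of these lists were not called. Some microglia and macrophage markers rose beside them, and which captured cells carried the immune transcripts was not tested. Interferon response and antigen presentation genes gave 10 higher and 0 lower of 19 by either adjustment (median 3.18, camera adjusted p = 0.00407, but adjusted p = 0.13 with an estimated correlation). The class II gene H2-Aa was at 11.2 ± 2.41 CPM against 0, at least 38.3-fold higher (adjusted p = 0.000249), and Ifi27, an interferon-induced gene, rose by 3.15 ± 0.52 (adjusted p = 0.000438). Microglia and macrophage markers gave 6 higher and 0 lower of 16 by either adjustment (median 1.43, camera adjusted p = 0.125, and 0.0292 without normal replicate 1 or 0.0389 with a filter of CPM 10). Laptm5, a lysosomal protein of blood cells and microglia, rose by 2.69 ± 0.48 (adjusted p = 0.000816). Matrix and adhesion genes gave 9 higher and 0 lower of 23 by either adjustment (median 1.69, camera adjusted p = 0.0191, but adjusted p = 0.314 with an estimated correlation). Among them were the brain proteoglycan Ncan (3.43 ± 0.33, adjusted p = 6.73e-06) and the galectin Lgals1 (3.54 ± 0.35, adjusted p = 9.01e-06). Secreted factors and their receptors gave 6 higher and 1 lower of 23 by either adjustment (median 0.5, camera adjusted p = 0.125, and 0.0173 with a filter of CPM 10). Mdk rose by 3.06 ± 0.26 (adjusted p = 2.96e-06), Igf2 by 5.06 ± 0.56 (adjusted p = 2.06e-05) and Pdgfa, which drives oligodendrocyte precursors, by 1.65 ± 0.32 (adjusted p = 0.00139). The cytokine Il4 was near the floor, at 0.733 ± 0.448 against 3.74 ± 2.25 CPM (-2.33 ± 0.89, adjusted p = 0.0504); it passed with DESeq2 (adjusted p = 0.0244) and without normal replicate 3 (0.0373) or 4 (0.0474). Igf1 was 1.65 ± 0.669 against 4.63 ± 3.65 CPM (adjusted p = 0.115). Shh, the Hedgehog ligand, had too few counts to be tested: 15 in tumor-derived replicate 4, 1 in normal replicate 1, 2 in GNP replicate 1 and 0 in every other library.

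Ribosomal protein genes gave 65 higher and 1 lower of 76 (67 and 2 adjusted over the list alone), with a median of 1.65 (camera adjusted p = 2.04e-25, but adjusted p = 0.111 with an estimated correlation). Rps3, for example, rose by 2.15 ± 0.16 (adjusted p = 9.81e-07). Glycolysis genes gave 4 higher and 7 lower of 17 by either adjustment (median -0.99, camera adjusted p = 0.0931, and 0.0232 without tumor-derived replicate 1). The lactate dehydrogenase subunit Ldha rose by 1.32 ± 0.19 (adjusted p = 0.000161), while Ldhb fell by 1.55 ± 0.26 (adjusted p = 0.000465). Cholesterol synthesis genes gave 2 higher and 1 lower of 15 by either adjustment (median 0.23, camera adjusted p = 0.665). Oligodendrocyte lineage genes gave 3 higher and 3 lower of 13 (4 and 4 adjusted over the list alone; camera adjusted p = 0.907), with a median of -1.15 and a test that pointed down but a mean of 0.03. Cspg4, a proteoglycan of oligodendrocyte precursors, rose by 4.22 ± 0.58 (adjusted p = 0.00012), while Cnp, of mature myelin, fell by 1.61 ± 0.31 (adjusted p = 0.00139). Vascular markers gave 1 higher and 2 lower of 15 (0 and 0 adjusted over the list alone; camera adjusted p = 0.96), with a median of 0.13 and a mean of 0.2 where the test pointed down. Cldn5, a tight junction protein of brain endothelium, was 144 ± 18.1 against 72.6 ± 22.5 CPM (adjusted p = 0.0205, and 0.0535 without tumor-derived replicate 2). Hemoglobin genes gave 0 higher and 3 lower of 5 (0 and 4 adjusted over the list alone), with a median of -3.4 (camera adjusted p = 0.0183, but adjusted p = 0.157 with an estimated correlation). Hbb-bs was 106 ± 52.6 against 1042 ± 642 CPM (adjusted p = 0.000258). Immediate early and heat shock genes gave 1 higher and 5 lower of 13 (1 and 6 adjusted over the list alone), with a median of -1.24 (camera adjusted p = 0.042, but adjusted p = 0.156 with an estimated correlation). The camera call was lost without normal replicate 2 (0.0724) or 3 (0.0856) and without tumor-derived replicate 1 (0.0615) or 3 (0.0788), and with a filter of CPM 10 (0.321).

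Against GNPs, tumor-derived astrocytes carried higher levels of many astrocyte, microglial, vascular and neuronal transcripts, while Mki67 and Gli1 were not called between them. Aldh1l1 was 274 ± 58.4 CPM in tumor-derived astrocytes (n = 4) and 0.843 ± 0.0179 CPM in GNPs (n = 2), and the microglial complement gene C1qb was 358 ± 90.1 against 0.036 ± 0.0509 CPM. Mki67 was 872 ± 147 against 945 ± 19.1 CPM (log2 fold change -0.12 ± 0.37, adjusted p = 0.823) and Gli1 65.0 ± 5.63 against 49.3 ± 11.2 CPM (0.28 ± 0.81, adjusted p = 0.815). Of 14393 genes 2900 were higher and 1852 lower (edgeR, adjusted p under 0.05), which dropped to 1129 and 628 once the GNP trio was combined. Without tumor-derived replicate 2 the count of lower genes in the first fit was 1213. Differences below pass both fits, and list counts are given as those of the planned fit followed by those of the combined fit. Adjusted p and standard errors below are of the planned fit unless said otherwise. It counts the close trio as separate libraries, so these values are too small if the trio is a single sample. With the trio combined, all 66 list tests over the comparisons kept their camera call. Whether GNPs had been in culture is not settled, so culture cannot be separated from cell type.

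Astrocyte markers were higher as a group, 19 of 24 with 0 lower (13 and 0 combined; 19 and 1 adjusted over the list alone). The median was 2.64, or 2.41 at the bound (camera adjusted p = 1.02e-11, and adjusted p = 0.0399 with an estimated correlation). Aldh1l1 was higher by 8.32 ± 0.58 (adjusted p = 1.77e-06) and the lipid carrier Apoe by 5.54 ± 0.50 (adjusted p = 9.59e-06) on the log2 scale. Aqp4 was 8.79 ± 2.63 against 0.017 ± 0.024 CPM (adjusted p = 3.12e-05). Gfap (1.92 ± 0.97, adjusted p = 0.142) and Sox9 (-2.4 ± 0.91, adjusted p = 0.0575) did not pass. Gfap passed with limma voom (adjusted p = 1.13e-07) and in the fit of 2 groups (adjusted p = 0.000576), with a range of 1.13e-07 to 0.419 over 15 alternatives. Sox9 passed in those fits, with DESeq2 and without GNP replicate 3 (adjusted p = 0.0477). Here and below, these alternatives counted the close GNP trio as separate libraries, and limma voom gave them weights of 6.4 to 10.8. Slc1a3 was 85.5 ± 20.4 against 25.9 ± 3.05 CPM, with an adjusted p of 0.037 in the planned and 0.189 in the combined fit. Bergmann and radial glia markers gave 8 higher and 1 lower of 11 (3 and 1 combined; 10 and 1 adjusted over the list alone), with a median of 2.85 (camera adjusted p = 0.000313, but adjusted p = 0.229 with an estimated correlation). Timp4 was higher by 6.14 ± 0.44 (adjusted p = 2.05e-06), while Vim, an intermediate filament of immature cells, was lower by -1.59 ± 0.27 (adjusted p = 0.000823). Genes of astrocyte specification gave 3 higher and 3 lower of 17 (2 and 2 combined; 3 and 4 adjusted over the list alone; camera adjusted p = 0.36), with a median of -0.28, a test that pointed down and a mean of 0.1.

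Microglia and macrophage markers were higher, 14 of 16 with 0 lower (12 and 0 combined; 14 and 0 adjusted over the list alone). The median was 7.34, or 6.26 with 4 members at their bound (camera adjusted p = 2.48e-14, and adjusted p = 0.017 with an estimated correlation). Vascular markers gave 9 higher and 0 lower of 15 (5 and 0 combined; 10 and 0 adjusted over the list alone; median 3.48; camera adjusted p = 1.01e-06, and adjusted p = 0.00404 with an estimated correlation). The 8 genes of largest excess were Aif1, Cldn5, S100a1, Gabrd, Trem2, Wnt7a, C1qb and Pcp2, with adjusted p of 5.61e-07 to 0.000137. C1qb aside, they were at 0 in every GNP library. Aif1 and Trem2, of microglia, were at least 490-fold and 248-fold higher, and Cldn5 at least 457-fold. S100a1, a calcium-binding protein, was at least 453-fold higher, Gabrd, a GABA receptor subunit of granule neurons, at least 357-fold, Wnt7a at least 236-fold and Pcp2 at least 214-fold. Pcp2 stood at 166 CPM in tumor-derived replicate 1 and at 32.5 to 37.2 CPM in the others, and its fitted log2 fold change of 12.34 was 11.43 without that library. C1qb had its only 2 GNP counts in replicate 1. Purkinje, interneuron and synaptic genes gave 14 higher and 0 lower of 16 (11 and 0 combined; 14 and 0 adjusted over the list alone), with a median of 3.63, or 3.41 at the bound (camera adjusted p = 1.85e-10, but adjusted p = 0.101 with an estimated correlation). Pvalb, of interneurons and Purkinje cells, was at 1185 ± 348 against 109 ± 21.5 CPM (adjusted p = 9.18e-05). Granule neuron genes gave 6 higher and 2 lower of 18 (5 and 0 combined; 6 and 2 adjusted over the list alone; median 0.35, or 0.34 at the bound; camera adjusted p = 0.258). Among them were the RNA-binding proteins Rbfox3 (2.95 ± 0.52, adjusted p = 0.0011) and Elavl3 (1.6 ± 0.28, adjusted p = 0.00102). Over 16 alternatives these adjusted p reached 0.0228 and 0.0332. Oligodendrocyte lineage genes gave 8 higher and 0 lower of 13 (4 and 0 combined; 11 and 0 adjusted over the list alone), with a median of 3.94, or 2.61 at the bound (camera adjusted p = 4.67e-05, but adjusted p = 0.0705 with an estimated correlation). Cnp was higher by 4.08 ± 0.35 (adjusted p = 7.52e-06). Hemoglobin genes gave 3 higher and 0 lower of 5 (3 and 0 combined; 5 and 0 adjusted over the list alone), with a median of 7.26, or 2.97 at the bound (camera adjusted p = 8.76e-05, but adjusted p = 0.0572 with an estimated correlation).

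Interferon response and antigen presentation genes gave 11 higher and 1 lower of 19 (7 and 0 combined; 12 and 2 adjusted over the list alone), with a median of 3.46 (camera adjusted p = 0.00126, and adjusted p = 0.0399 with an estimated correlation). Irf7, a master regulator of interferon genes, was at 0 in GNPs and at least 117-fold higher in tumor-derived astrocytes (adjusted p = 0.000237). Matrix genes gave 10 higher and 0 lower of 23 (4 and 0 combined; 11 and 1 adjusted over the list alone), with a median of 1.47 (camera adjusted p = 0.00176, but adjusted p = 0.101 with an estimated correlation). Higher members were the proteoglycans Bcan (2.94 ± 0.28, adjusted p = 1.34e-05) and Ncan (3.28 ± 0.33, adjusted p = 1.98e-05). Secreted factors and receptors gave 10 higher and 0 lower of 23 (2 and 0 combined; 10 and 1 adjusted over the list alone; median 0.8; camera adjusted p = 0.0913). The 2 were Il4ra, the receptor chain for Il4, at 37.7 ± 8.34 against 0.16 ± 0.226 CPM (adjusted p = 2.34e-05), and Pdgfa (2.39 ± 0.33, adjusted p = 0.000219). Il4 itself was 0.733 ± 0.448 against 1.77 ± 2.07 CPM (adjusted p = 0.138, but 0.0465 without GNP replicate 3 and 0.00304 with limma voom) and Igf1 1.65 ± 0.669 against 4.02 ± 0.771 CPM (adjusted p = 0.218, but 0.0397 with limma voom). Pan-reactive genes gave 2 higher and 1 lower of 11 (0 and 1 combined; 2 and 1 adjusted over the list alone; median 1.92; camera adjusted p = 0.56). A1 genes gave 2 higher and 0 lower of 8 (1 and 0 combined; 2 and 0 adjusted over the list alone; median 1.29; camera adjusted p = 0.235). A2 genes gave 2 higher and 1 lower of 6 (1 and 0 combined; 2 and 1 adjusted over the list alone; camera adjusted p = 0.846), with a median of -0.82 and a mean of 1.29. Glycolysis genes gave 10 higher and 0 lower of 17 in both fits and over the list alone, with a median of 1.27 (camera adjusted p = 3.8e-06, and adjusted p = 0.045 with an estimated correlation). Eno1 led these (2.7 ± 0.18, adjusted p = 1.51e-06).

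Lower in tumor-derived astrocytes than in GNPs were some cell cycle and cholesterol synthesis genes, and many members of both lists were not called once the trio was combined. Of 40 cell cycle genes 15 were lower and 0 higher (4 and 0 combined; 16 and 0 adjusted over the list alone), with a median of -1.22 (camera adjusted p = 8.16e-06, and adjusted p = 0.00404 with an estimated correlation). Ube2c was 62.9 ± 28.3 against 289 ± 50.5 CPM (-2.28 ± 0.33, adjusted p = 0.000673) and the spindle checkpoint kinase Bub1b 28.2 ± 6.38 against 108 ± 14.3 CPM (-2.0 ± 0.29, adjusted p = 0.000673). Of 15 cholesterol genes 12 were lower and 0 higher (6 and 0 combined; 13 and 0 adjusted over the list alone), with a median of -1.98 (camera adjusted p = 6.09e-07, and adjusted p = 0.0102 with an estimated correlation). Msmo1, a sterol oxidase, was lower by -3.29 ± 0.39 (adjusted p = 7.52e-05) and Sqle, a rate-limiting sterol enzyme, by -2.35 ± 0.29 (adjusted p = 9.39e-05). Granule progenitor markers gave 1 higher and 2 lower of 15 (0 and 0 combined; 1 and 2 adjusted over the list alone; median -0.2; camera adjusted p = 0.301). Atoh1 was 6.47 ± 4.54 against 40.8 ± 22.8 CPM, with an adjusted p of 0.00322 in the planned and 0.0509 in the combined fit, and Zic1 97.3 ± 4.93 against 65.7 ± 4.84 CPM (adjusted p = 0.12, but 0.00155 with limma voom and 0.0116 in the fit of 2 groups). The fitted log2 fold change of Atoh1 was -2.91, and -3.53 without tumor-derived replicate 4. Hedgehog genes gave 2 higher and 2 lower of 13 (0 and 0 combined; 2 and 2 adjusted over the list alone; median -0.59; camera adjusted p = 0.391). Ptch1 was at 8.44 ± 1.51 against 2.97 ± 1.56 CPM (adjusted p = 0.0323, combined 0.143, and 0.0884 with no filter). Immediate early and heat shock genes gave 1 higher and 2 lower of 13 (0 and 1 combined; 2 and 4 adjusted over the list alone; median -0.58; camera adjusted p = 0.271). The 1 was the chaperone Hspa5 (-1.24 ± 0.23, adjusted p = 0.00147). Ribosomal protein genes gave 14 higher and 15 lower of 76 (9 and 6 combined; 14 and 16 adjusted over the list alone; median -0.05; camera adjusted p = 0.258, and 0.0476 without tumor-derived replicate 1). The 8 genes lowest against GNPs were Ttc39d, Omd, Lrif1, Zfp947, Insl5, Zfp758, S1pr5 and Als2cl, all at low levels, with GNP means of 0.878 to 7.14 CPM. Of these 6 passed both fits, and Zfp947 (combined adjusted p = 0.0802) and Insl5 (0.113) did not. Ttc39d, Omd and Lrif1 were at 0 in every tumor-derived library and at least 21.1-fold, 9.25-fold and 6.9-fold lower. Als2cl had 2 tumor-derived counts, both in replicate 3, and Zfp758 had 1, in replicate 4.

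Normal astrocytes and GNPs, the reference groups, differed in most tested cell cycle genes, astrocyte markers and markers of Purkinje cells, interneurons and synapses. Pcp2 was 3053 ± 1444 CPM in normal astrocytes (n = 4) and 0 in every GNP library (n = 2), at least 9690-fold higher, and Aldoc was 6956 ± 3299 against 35.1 ± 25.9 CPM. Mki67 was 0.275 ± 0.424 against 945 ± 19.1 CPM and Atoh1 0 against 40.8 ± 22.8 CPM, at least 139-fold lower. In all, 3423 genes were higher and 2933 lower in normal astrocytes (edgeR, adjusted p under 0.05), and 1929 and 2023 with the GNP trio combined, of which 1929 and 2006 were called in both. With upper quartile factors the planned fit gave 2945 higher and 3511 lower, which turns the balance between directions. Adjusted p and standard errors of this comparison are again of the planned fit, and too small if the GNP trio is a single sample.

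Astrocyte markers were higher in normal astrocytes, 20 of 24 with 0 lower (17 and 0 combined; 21 and 0 adjusted over the list alone; median 3.89; camera adjusted p = 2.68e-14, and adjusted p = 0.0416 with an estimated correlation). Aldoc was higher by 7.29 ± 0.55 on the log2 scale (adjusted p = 4.93e-07) and Aldh1l1 by 8.14 ± 0.58 (adjusted p = 2.72e-07). Aqp4 (20.7 ± 9.47 against 0.017 ± 0.024 CPM, adjusted p = 2.87e-06) and Slc1a3 (304 ± 280 against 25.9 ± 3.05 CPM, adjusted p = 0.00047) were higher. Slc1a3 had a log2 fold change of 3.49, and 2.76 without normal replicate 3. Gfap was 11.2 ± 19.9 against 26.3 ± 5.24 CPM (-1.13 ± 0.95, adjusted p = 0.358); without normal replicate 2 it was lower by -4.27 (adjusted p = 1.02e-05), and limma voom also called it (-3.18, adjusted p = 0.0271). Sox9 did not pass (adjusted p = 0.262). Bergmann glia markers gave 7 higher and 2 lower of 11 (6 and 2 combined; 8 and 2 adjusted over the list alone; median 3.71; camera adjusted p = 0.0245, but adjusted p = 0.513 with an estimated correlation and 0.196 with a filter of CPM 10). Nes was lower by -2.77 ± 0.34 (adjusted p = 2.7e-05). Genes of astrocyte specification gave 2 higher and 3 lower of 17 (1 and 2 combined; 2 and 2 adjusted over the list alone; camera adjusted p = 0.535), with a median of -0.3, a test that pointed down and a mean of 0.18. The neuron list gave 15 higher and 1 lower of 16 by every count (median 7.35, or 7.36 at the bound; camera adjusted p = 4.59e-16, and adjusted p = 0.0497 with an estimated correlation). Granule neuron genes gave 10 higher and 2 lower of 18 (8 and 2 combined; 11 and 2 adjusted over the list alone; median 1.31; camera adjusted p = 0.00371, but adjusted p = 0.27 with an estimated correlation). The 8 genes of largest excess, Pcp2, Gabrd, Gng13, Ppp1r17, Itpka, Fam107a, Wnt7a and Kcng4, were at 0 in every GNP library and at least 921-fold to 9690-fold higher (adjusted p of 1.38e-07 to 0.000157). Several of these are genes of Purkinje or granule neurons. The fitted log2 fold change of Fam107a was 14.97, and 14.38 without normal replicate 4, and that of Wnt7a was 14.71, and 14.04 without normal replicate 2.

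Many markers of microglia, vessels, oligodendrocytes and blood were also higher. Microglia markers gave 14 higher and 0 lower of 16 (13 and 0 combined; 14 and 0 adjusted over the list alone), with a median of 5.9, or 5.53 at the bound (camera adjusted p = 3.9e-07, but adjusted p = 0.0843 with an estimated correlation). Vascular markers gave 11 higher and 0 lower of 15 (6 and 0 combined; 11 and 0 adjusted over the list alone; median 3.28; camera adjusted p = 0.000108, and adjusted p = 0.0262 with an estimated correlation). Oligodendrocyte genes gave 9 higher and 1 lower of 13 (6 and 1 combined; 9 and 1 adjusted over the list alone), with a median of 5.3, or 2.93 at the bound (camera adjusted p = 0.00263, but adjusted p = 0.176 with an estimated correlation). Hemoglobin genes gave 5 higher and 0 lower of 5 by every count, with a median of 10.97, or 6.52 at the bound (camera adjusted p = 3.1e-05, and adjusted p = 0.0497 with an estimated correlation). Glycolysis genes gave 12 higher and 1 lower of 17 by every count (median 1.55; camera adjusted p = 3.82e-07, and adjusted p = 0.0416 with an estimated correlation). Tpi1 was higher by 3.07 ± 0.22 (adjusted p = 3.69e-07). Immediate early and heat shock genes gave 4 higher and 2 lower of 13 (3 and 1 combined; 4 and 2 adjusted over the list alone; median 0.83; camera adjusted p = 0.358). Interferon genes gave 7 higher and 4 lower of 19 (3 and 3 combined; 8 and 5 adjusted over the list alone), with a median of 1.37, or 0.83 at the bound (camera adjusted p = 0.889). Pan-reactive genes gave 1 higher and 2 lower of 11 (0 and 2 combined; 1 and 1 adjusted over the list alone; camera adjusted p = 0.535), with a median of -0.96, a test that pointed down and a mean of 0.02. A1 genes gave 2 higher and 1 lower of 8 (1 and 0 combined; 2 and 1 adjusted over the list alone; camera adjusted p = 0.889), with a median of 0.46, a test that pointed up and a mean of -0.15. A2 genes gave 2 higher and 1 lower of 6 (1 and 1 combined; 2 and 1 adjusted over the list alone; camera adjusted p = 0.969), with a median of 0.32, or 0.31 at the bound, and a mean of 0.49 where the test pointed down. Secreted factors gave 6 higher and 4 lower of 23 (4 and 2 combined; 6 and 4 adjusted over the list alone; camera adjusted p = 0.926), with a median of 0.3 and a mean of 0.75 where the test pointed down. Il4 (adjusted p = 0.608) and Igf1 (adjusted p = 0.752) did not pass. Matrix genes gave 5 higher and 2 lower of 23 (3 and 2 combined; 5 and 2 adjusted over the list alone; camera adjusted p = 0.926), with a median of -0.12, a mean of 0.5 and a test that pointed up.

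Lower in normal astrocytes were most cell cycle genes and many granule progenitor, Hedgehog, cholesterol and ribosomal protein genes. Cell cycle genes gave 38 lower and 0 higher of 40 (37 and 0 combined; 39 and 0 adjusted over the list alone), with a median of -6.62, or -6.06 at the bound (camera adjusted p = 9.78e-38, and adjusted p = 1.08e-05 with an estimated correlation). Mki67 was lower by -11.82 ± 0.63 (adjusted p = 3.72e-08), or -13.65 without normal replicate 2. The 8 genes of largest deficit, Ube2c, Igfbpl1, Pif1, Hsd11b2, Fam64a, Tnnt3, Bub1b and Cdca5, were at 0 in every normal library and at least 337-fold to 983-fold lower (adjusted p of 3.72e-08 to 0.000202). Granule progenitor markers gave 11 lower and 1 higher of 15 (10 and 0 combined; 11 and 1 adjusted over the list alone; median -3.31; camera adjusted p = 2.19e-06, and adjusted p = 0.00543 with an estimated correlation). Atoh1 was called with an adjusted p of 5.44e-06, while Zic1, 127 ± 48.3 against 65.7 ± 4.84 CPM, had an adjusted p of 0.00985 in the planned and 0.106 in the combined fit. Hedgehog genes gave 8 lower and 2 higher of 13 (6 and 1 combined; 9 and 2 adjusted over the list alone; median -2.35; camera adjusted p = 0.000228, but adjusted p = 0.0921 with an estimated correlation). Gli1 was lower by -5.16 ± 0.99 (adjusted p = 0.00099; -6.94 without normal replicate 4) and Ptch1 higher by 2.71 ± 0.43 (adjusted p = 0.000243). Cholesterol genes gave 11 lower and 0 higher of 15 by every count (median -2.38; camera adjusted p = 2.82e-05, but adjusted p = 0.0572 with an estimated correlation). Ribosomal protein genes gave 68 lower and 1 higher of 76 (62 and 0 combined; 72 and 2 adjusted over the list alone; median -1.67; camera adjusted p = 3.9e-24, but adjusted p = 0.0572 with an estimated correlation).

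Some genes of several lists were higher in tumor-derived astrocytes than in both other groups, and none of these lists was tested for an excess of them. The captured cells that carried these transcripts were not identified. H2-Ab1, a class II antigen presentation gene, was 64.2 ± 44.3 CPM in tumor-derived astrocytes against 0.769 ± 0.888 CPM in normal astrocytes and 0.018 ± 0.0255 CPM in GNPs. Its log2 fold change against normal astrocytes was 6.35, or 6.96 without normal replicate 4, and its only GNP count was in replicate 1. Ncan was 159 ± 54.6 CPM against 14.8 ± 2.97 and 17.3 ± 2.63 CPM, and Nes 502 ± 135 CPM against 17.1 ± 6.75 and 128 ± 31.4 CPM. A total of 875 genes were higher than in both groups and 782 lower (edgeR, adjusted p under 0.05 in both comparisons), of which 351 and 317 also passed with the GNP trio combined. Without tumor-derived replicate 2 or 3, 484 and 502 genes were lower than in both groups. Both comparisons share the tumor-derived libraries. Independent lists of these sizes would share 600.4 and 357.2 genes. Simulated unchanged groups shared a median of 0, but no gene was called there in either comparison, so this sets no scale. At an unadjusted edgeR p under 0.05, a looser threshold, they shared a median of 47 higher (34 to 53) and 107 lower genes (81 to 122). When different pairs of the tumor-derived libraries served each comparison, the median over 6 splits was 508 (499 to 515) and 311.5 (282 to 360). Each comparison then held fewer libraries, so these counts cannot be set directly against the others.

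Of the interferon and antigen presentation genes, 7 of 19 were higher than in both groups in both fits: H2-Ab1, H2-Aa, Cd74, Bst2, Ifitm3, Irf7 and Ifi27. Microglia markers gave 5 of 16 (Lyz2, Aif1, Trem2, Laptm5 and C1qb), glycolysis genes 3 of 17 (Ldha, Gapdh and Eno1), matrix genes 2 of 23 (Ncan and Timp2), oligodendrocyte lineage genes 2 of 13 (Sox10 and Cspg4) and granule neuron genes 2 of 18 (Cntn2 and Elavl3). Single members came from the lists of Bergmann glia (Nes), A1 genes (Psmb8), secreted factors (Pdgfa) and vascular markers (Cldn5). Ribosomal protein genes gave 9 of 76 higher and 1 lower, and Hspa5 (84.5 ± 16.6 CPM against 386 ± 64.1 and 226 ± 75.5 CPM) was lower than in both groups. Ifi27 stood at 136 CPM in tumor-derived replicate 1 and at 1197 to 1235 CPM in the others, and Sox10 at 1.87 CPM in that replicate and at 34.8 to 49.3 CPM in the others. Both values of replicate 1 lay inside the normal range (67 to 144 and 0.473 to 3.78 CPM), as did that of Cntn2 (218 CPM, normal 66.6 to 260 CPM). Of the astrocyte markers and cell cycle genes, 0 of 24 and 0 of 40 were higher or lower than in both groups in both fits.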

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

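The tests of RNA mixing, of neuronal RNA and of the close GNP libraries were chosen after the results they measure were seen, while the search for far libraries and the regrouping of libraries were planned. In each group of 4 libraries, a library was called far from the others when its gap to the nearest exceeded Dixon's critical share of the group's range. Chance passes that limit in about 1 in 20 groups of normally distributed values. The search covered normal and tumor-derived astrocytes for 107 genes named in the report, 22 lists and 3 library measures. Of 264 groups, 32 passed the limit, where that rate would give 13.2, and several of these groups held a single count. CPM need not be normally distributed, and genes and lists share libraries and members. The excess over 13.2 therefore does not show that these libraries differ beyond chance.

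Tumor-derived replicate 1 was far from the others for several genes. It was high in the Purkinje cell genes Pcp2 (165.8 CPM, others 32.53 to 37.23), Ppp1r17 (17.96 CPM) and Itpr1 (53.24 CPM, others 20.76 to 24.29). It was also high in the troponins Tnnt1 (236.3 CPM) and Tnnt3 (60.48 CPM) and in Aqp4 (12.72 CPM). It was low in Ifi27 (135.7 CPM, others 1197 to 1235), Ncan (77.93 CPM), Chaf1b (70.33 CPM) and the secreted factor list (mean log2 CPM 2.23, others 3.06 to 3.19). Tumor-derived replicate 2 was high in Gfap (152.4 CPM), Sox9 (1.229 CPM), Kcng4 (6.143 CPM) and the immediate early and heat shock list (mean log2 CPM 3.85), and held the only counts of Comp (0.2457 CPM) in its group. Replicate 3 was low in Cspg4 (26.03 CPM) and held the only counts of Als2cl in its group (0.2169 CPM). Replicate 4 was high in Atoh1 (13.24 CPM), held the only counts of Shh (1.439 CPM), and the only ones of Zfp947 and Zfp758 (0.09595 CPM each).

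Among normal libraries, replicate 2 was high in Gfap (41.08 CPM, others 0.9458 to 1.756), Tubb3 (103.8 CPM), Mki67 (0.9078 CPM) and Lrif1 (1.021 CPM). Replicate 3 was high in Zfp947 (59.5 CPM) and S1pr5 (28.2 CPM). Replicate 4 was high in Hbb-bs (1995 CPM), Als2cl (2.732 CPM) and Zfp758 (1.073 CPM), and held the only count of Slc17a6 (0.09758 CPM). Replicate 1 held the only count of Shh (0.09456 CPM).

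Cell cycle, granule progenitor and Hedgehog target transcripts were present in all tumor-derived astrocyte libraries, at levels near those of GNPs for Mki67 and Gli1. In a mixture of RNA like that of the normal libraries and RNA like that of the GNP libraries, genes that normal astrocytes lack would all stand at the same share of their GNP level. Of 38 list members at under 5% of their GNP level in normal astrocytes, 1 differed from the median share by over 1.5 times at an adjusted p under 0.05 (limma, libraries centred on the median of these members, GNP trio combined). That was Gli1 (log2 fold change 1.6 ± 0.2, adjusted p = 0.0374). The quartiles of the 38 were -1.06 and 0.76, wider than 1 share would give without noise, so the test neither supports nor excludes the mixture. Outside the 38, Hhip was at 15.04 ± 3.531 CPM in tumor-derived astrocytes against 0.208 ± 0.2472 in normal astrocytes and 0.7516 ± 0.6227 in GNPs, a place that such a mixture would not give. Hhip and Pax6 were above both groups and Cdon below both in the planned fit, which goes against the mixture for these genes. With the GNP trio combined the adjusted p against GNPs was 0.0664, 0.17 and 0.13, and the calls of Pax6 and Cdon were also lost without single libraries. Of these lists 0 members thus passed both fits, and the mixture stays open for the lists as a whole. Over all tested genes, 351 were higher and 317 lower in tumor-derived astrocytes than in both other groups in both fits. A mixture of these kinds of RNA alone would place each gene between the groups. For those genes the values argue against it as the sole make-up of the libraries. RNA of tumor cells in place in the tissue, whose profile the captured GNPs need not match, also remains open. Expression of the cell cycle, granule progenitor and Hedgehog genes by the astrocytes themselves is the biological alternative and was not tested apart from it. Captured cells cannot be told from their neighbours in counts of this kind.

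Purkinje, interneuron and synaptic transcripts were higher in normal than in tumor-derived astrocyte libraries. Of 16 members of that list 15 reached 10 CPM in each normal library, against 4 in each GNP library, but this restates that the list is high in those libraries and so neither supports nor excludes RNA of cerebellar neurons captured with the astrocytes. Such RNA would dilute transcripts that neurons lack in the normal libraries and so raise the astrocyte list in tumor-derived ones. That list had a median of -1.2 (quartiles -2.1 and -0.25), so dilution by neuronal RNA does not account for its fall. The median was known when this test was chosen, and list members were not examined for expression in neurons. The test therefore does not exclude neuronal RNA in the normal libraries. A loss of neurons around the captured cells in tumor, a difference in age, and neuronal transcripts within astrocytes stay open and were not tested.

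GNP libraries 1, 2 and 4 were much closer to each other than other libraries of 1 group. Over genes with few counts, their highest chi-square per degree of freedom was 1.62, against 4.2 for the lowest of the other pairs, which restates the closeness that raised the question. Over all genes with at least 10 counts it was 1.43 for libraries 2 and 4 but 7.52 and 6.59 for library 1 with each of these, beyond counting noise. The deposited titles give the libraries different numbers, which speaks for separate samples but does not say what is numbered. Whether 1 amplified sample was divided into these libraries therefore stays open. Separate samples of cells of unusually even state, whether captured from tissue or cultured, are the untested biological alternative. Every comparison with GNPs was therefore also made with these libraries combined.

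Among the 35 splits of the 8 libraries of each comparison into 4 and 4, the real one was the 1 with the most genes called in each. Tumor-derived against normal astrocytes gave 5756 genes and at most 0 in another split, tumor-derived astrocytes against GNPs 4752 and at most 1, and normal astrocytes against GNPs 6356 and at most 49. For the first of these counts, chance assignment of independent libraries would put the real split first in 1 of 35 cases, the smallest share possible. With GNP libraries 1, 2 and 4 as 1 unit the others have 15 assignments, too few for a share under 0.05. Libraries that share an animal are not separated by this test.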

How the results depend on the processing

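The fit with GNP libraries 1, 2 and 4 counted as 1 was added after the data were seen, and the other alternatives were planned. Single genes were followed only where the rule for named genes took them, mostly for large or clear differences, so other called genes were not examined. Among those followed, no called gene reversed in an alternative run on it, and no called list or similarity difference did. Upper quartile factors and the fit without robust dispersion were run only on counts of genes, and lists were not run with these, DESeq2, limma voom, TMMwsp, the fit of 2 groups or no filter. With the trio counted as 1, tumor-derived astrocytes against GNPs gave 1129 genes higher and 628 lower, normal astrocytes against GNPs 1929 higher, and genes apart from both groups 352 and 317. The similarity difference was then -0.0663 and the positions 0.47 and 0.782. Limma voom, which gave the trio weights of 6.4 to 10.8, called 5789 genes higher and 4886 lower against GNPs and 1865 and 1227 apart from both. A fit of only the 2 groups gave 3184 lower than GNPs. The position of genes higher in GNPs was 0.746 with RLE factors, 0.682 with no filter and 0.757 with a prior count of 0.5. Without 1 library at a time, genes lower in tumor-derived astrocytes than in GNPs ranged from 1213 (without tumor-derived replicate 2) to 2132, and genes lower than in both groups from 484 (without tumor-derived replicate 2) to 909. Without 1 library at a time the similarity difference ranged from -0.0628 to -0.0345, the position of genes higher in normal astrocytes from 0.38 to 0.468 and that of genes higher in GNPs from 0.632 to 0.765. Over the single genes that the rule took, 4736 alternative values left the call as it was, 170 ended it and 17 made one, and for lists 841, 29 and 45. Of the list calls lost, 21 came from the estimated correlation. Of those gained, 11 came from the directional and 29 from the mixed form of fry, which sets members against no change, where camera sets them against other genes. Between tumor-derived and normal astrocytes directional fry gave an adjusted p of 0.00182 for pan-reactive, 0.000618 for A1, 0.000153 for secreted factor and 0.00404 for microglia genes, all upward. Glycolysis genes went downward (directional fry, adjusted p = 0.00404). Upper quartile factors gave 3444 genes higher and 2289 lower in tumor-derived than in normal astrocytes, 2856 and 1918 against GNPs, and 2945 and 3511 in normal astrocytes against GNPs. They shifted the median log2 fold change of all genes to 0.254 between tumor-derived and normal astrocytes and to -0.214 between normal astrocytes and GNPs, and RLE factors to 0.125 between tumor-derived astrocytes and GNPs. No paired analysis was possible because the labels give no animal or pair. An alternative without mitochondrial genes gave no values, because those genes held 0 counts.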

Other observations

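All observations here were chosen after the data were seen. A total of 348 genes had counts in every tumor-derived library and in none of the other 8. Of these, 29 had enough counts to be tested, and all 29 were called higher than in both groups in both fits. They were picked for that difference, so these calls and the adjusted p given below are no separate support. Tumor-derived libraries also held more genes with a count (19174 to 20460) than normal (14768 to 16306) or GNP libraries (16633 to 17938). Genes found only in another group were not counted. Pou3f4, a transcription factor of neural development, was at 32.72 ± 16.38 CPM (adjusted p = 0.000276 against normal astrocytes and 0.000456 against GNPs). Slamf9 (13.93 ± 5.853 CPM), Itgax (9.488 ± 4.202 CPM) and Cst7 (9.304 ± 6.575 CPM) were also among the 29 (adjusted p of 0.000553, 0.000804 and 0.00225 against normal astrocytes and 0.000863, 0.00125 and 0.00336 against GNPs). Larp1b, an RNA-binding protein, was at 1.337 ± 0.3329 CPM in tumor-derived astrocytes against 22.61 ± 19.07 CPM in normal astrocytes and 16.8 ± 15.1 CPM in GNPs.

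The ratio of mean CPM in tumor-derived astrocytes to that in GNPs spread widely over genes of the tumor cell. It was 0.923 for Mki67 and 1.32 for Gli1, but 0.218 for Ube2c, 0.159 for Atoh1, 2.38 for Igfbpl1, 2.59 for Ccnd1 and 20 for Hhip, an inhibitor of Hedgehog signalling and target of it that was low in GNPs. Noise of amplification and a different state of tumor cells in tissue were not tested apart.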
